A study of Caenorhabditis elegans with 4 samples.

How the data were processed

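The series mapped where a GFP-tagged form of R02D3.7, a protein that the labels call a transcription factor, was bound to DNA in L4 hermaphrodites of Caenorhabditis elegans. The strain, OP218, carries a transgene with the tagged gene and an unc-119 rescue marker in an unc-119(ed3) background, and the worms were grown at 20 °C. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) enriches the DNA fragments crosslinked to a protein. Per the labels' protocols, worms were fixed with formaldehyde, chromatin was sonicated, and tagged protein was collected with antibodies against GFP, while a part of the same extract was kept as input DNA. The 4 libraries are 2 ChIP and 2 input libraries, each numbered 1 and 2 in the labels. The labels do not say whether the numbers stand for separate cultures, so differences between the lists may be technical. The p-values were computed over peaks, so they describe these lists and do not measure the spread between libraries.

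The authors deposited 3 peak lists, 1 for each ChIP library and a combined one, and no values of the input libraries were analysed here. Per the file headers and the peak records, coordinates are on WormBase WS190 and peaks were called with PeakSeq, which compares read density in a ChIP library with a control and corrects for testing many regions. The only score of a deposited peak is its q-value, a p-value adjusted for the number of regions tested, as the authors' peak caller gave it. The aligner, the read filters, the PeakSeq version, the control of each call and the way the replicates were combined are not given in the sources used here. Read depth, peak height and summit position were not analysed here, so the depth behind a peak is unknown. A q-value depends on depth as well as on binding, so counts and medians of q-values describe each list and are no measure of a difference in binding between lists. Ratios of scores between lists, and a score predicted from them, were used in the closing observations alone, where they rest on that ratio being alike among the peaks compared. Start and end of a peak were taken as 1-based inclusive positions.

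From these lists the number, width, covered length and strength of peaks were computed, with strength given as -log10 q. A peak was called shared if it overlapped a peak of the other list by at least 1 bp. The shared number was compared with 100000 circular shifts of 1 list within each chromosome (one-sided permutation test, with 10000 shifts for alternative settings), which keep peak number, width and spacing. Agreement of -log10 q was measured as Spearman's rho and Pearson's r over shared peaks, each replicate 2 peak being paired with the replicate 1 peak of largest overlap, and tested with 100000 permutations of the pairings (two-sided). Each combined peak was assigned to a class by whether it overlapped a peak of both, 1 or neither replicate. The number of peaks on each of the 6 chromosomes was tested with a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 6 chromosomes, and the share of peaks in the central 50% of the chromosomes was tested in the same way. Shares carry Wilson 95% intervals, except the central share, which like the observed-to-expected ratios carries an exact binomial 95% interval, all of which cover counting error only. Peaks are not independent replicates and cluster along the genome, so the binomial and Fisher's exact p-values are too small. The threshold was 0.05.

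The tests and the alternatives were fixed before the data were examined, apart from those named as added. The shares by rank, the split at the middle rank, the relation of width to strength and the central share of single chromosomes were added after the data were seen. The expectation for a chromosome was planned from its length. No sequence or annotation of WS190 was used here, so the span from base 1 to the furthest peak end in any list was taken instead, 100.086 Mb in all. On X this span ends with a single wide combined peak. The RefSeq gene table used here is on WBcel235, a different build, so none of its positions was used, and it served only for the current name of R02D3.7, rcat-1. For the same reason 3 planned results were not run: the share of peaks at promoters, the enrichment of the 24 gene lists fixed beforehand, and the enrichment of short sequences under peaks. No peak was assigned to a gene, and R02D3.7 and unc-119, which were to be reported in any case, were not placed on WS190. The rule for named peaks was to take the 20 combined peaks with the smallest q-values among those that overlap a peak of both replicates, and to give them by position alone where no annotation of the build was used. Any other region named was chosen after its values were seen.

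The statistics were tested on simulated lists. With peaks placed at random, the overlap test called 1 of 20 runs, and with 40% of peaks planted as shared it called 20 of 20 runs and found a median of 40.2%. The chromosome test, with 2590 simulated peaks in a run, called any chromosome in 2 of 100 runs without an effect. It called chromosome III in 100 of 100 runs with a planted ratio of 1.33, and the median ratio found was 1.33. Simulated peaks were drawn independently of each other, and planted shared peaks were exact copies. The runs therefore check the computation and do not show how the tests behave with clustered peaks. The alternatives tried were stricter overlap rules, the stronger 50% of each list, equal list lengths, short shifts, merging of nearby peaks, peaks found in both replicates, and each replicate list alone. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.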

Results

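R02D3.7 (rcat-1) tagged with GFP was immunoprecipitated from L4 hermaphrodites to find the genomic regions bound by the protein. The combined list of the 2 ChIP libraries held 2590 peaks, the list of replicate 1 held 1251 and the list of replicate 2 held 810. Peaks were narrow, with a median width of 199 bp in the combined list, 253 bp in replicate 1 and 243 bp in replicate 2. They covered 924 kb, 478 kb and 278 kb of the genome, respectively, and a single peak of 117 kb on chromosome X was part of the combined length. All coordinates are on WS190, and the strength of a peak is the -log10 of the authors' q-value. The lists give no read depth, so the numbers of peaks in the replicates cannot be set against the numbers of reads behind them.

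A minority of peaks in each list was strong. A q-value under 1e-10 was given to 371 peaks (14.3%) of the combined list, 215 (17.2%) of replicate 1 and 142 (17.5%) of replicate 2. Because q-values depend on depth, these shares and the medians describe each list by itself. The median -log10 q was 3.43 in the combined list, 3.27 in replicate 1 and 3.01 in replicate 2. Stronger peaks were wider. Across peaks, which are not independent replicates, Spearman's rho between width and -log10 q was 0.81 in the combined list, 0.87 in replicate 1 and 0.86 in replicate 2. At the other end, 415 combined peaks (16.02%) were shorter than 50 bp, against 105 (8.39%) in replicate 1 and 58 (7.16%) in replicate 2.

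The strongest combined peak found in both replicates lay on chromosome IV at 4748407 to 4750780, with a q-value of 1.02e-250, and its partners ranked 3 in replicate 1 and 2 in replicate 2. It was followed by a peak on chromosome II at 10387223 to 10389168 (q = 9.62e-237) and another on the same chromosome at 4298484 to 4300419 (q = 3.67e-225). Chromosome V carried a peak of similar strength at 5683732 to 5685891 (q = 4.72e-224), and chromosome III one at 2527861 to 2529801 (q = 3.09e-215). Within chromosome III, a pair of the named peaks lay close together, at 5678550 to 5680672 (q = 3.49e-197) and 5705154 to 5707313 (q = 4.05e-201). Further named peaks on chromosome III lay at 8357066 to 8359041 (q = 2.90e-190), 4752628 to 4755055 (q = 4.84e-185) and 12977481 to 12979387 (q = 2.50e-164).

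Among the remaining named peaks, 4 were on chromosome IV, at 384691 to 387304, 653715 to 655505, 5208943 to 5211150 and 16865135 to 16866567. Chromosome V held peaks at 11238792 to 11239952 and 19189081 to 19190960, and chromosome II held peaks at 10541832 to 10544276 and 10871788 to 10873169. Chromosome I had a single named peak, at 6214942 to 6216263 (q = 1.38e-131), as did chromosome X, at 16929424 to 16931922 (q = 2.15e-126). The 20 named peaks were 1161 to 2614 bp wide. Their partners all ranked within the first 26 peaks of replicate 1 and the first 31 of replicate 2. The map of combined peaks shows these positions along the 6 chromosomes.

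**Figure D1:**
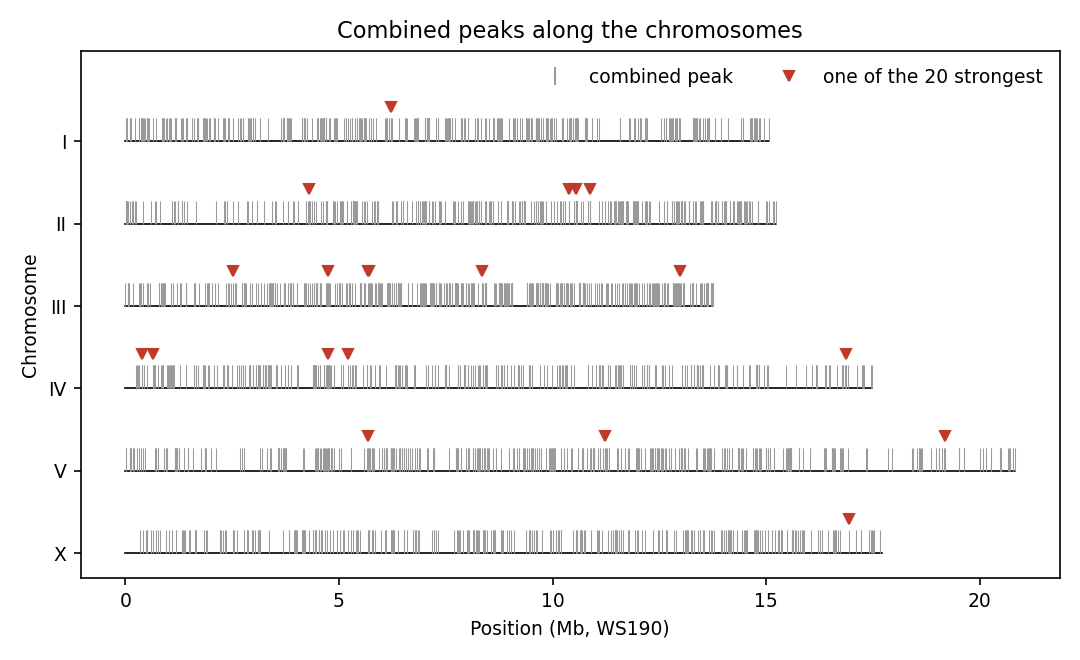
Positions of the 2590 combined peaks (grey lines) along the 6 chromosomes in Mb on WS190, with the 20 strongest that overlapped a peak of both replicates marked by red triangles. Chromosome III carried 6 of the 20 and chromosomes I and X carried 1 each, and neighbouring triangles on II and III partly coincide at this scale.

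The largest signal of each replicate list had no counterpart in the combined list. It lay near the left end of chromosome IV, at 254497 to 258513 in replicate 1 (q = 7.31e-304) and at 253160 to 258361 in replicate 2 (q = 6.70e-144), and ranked 1 in both. In all, 74 peaks of replicate 1 (5.92%) and 42 of replicate 2 (5.19%) overlapped no combined peak. Of these, 3 in each list overlapped a peak of the other replicate. The next strongest of the absent peaks had a q-value of 0.000326 in replicate 1 and 1.21e-07 in replicate 2.

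The strongest peaks were listed in both replicates and weak ones mostly were not. The largest q-value listed was 0.00959 in replicate 1 and 0.00975 in replicate 2. A region that falls just short in 1 library counts as absent there, so a missing partner does not show absent binding. Of the 810 peaks of replicate 2, 552 overlapped a peak of replicate 1 (68.1%, Wilson 95% interval 64.9 to 71.3), compared with a mean of 0.950% and a highest value of 14.6% in shifted lists. Of the 1251 peaks of replicate 1, 537 overlapped a peak of replicate 2 (42.9%, interval 40.2 to 45.7), compared with a mean of 0.614% and a highest value of 9.27%. The one-sided permutation p was 1e-05 in both directions, the smallest that 100000 shifts can give. A similar number of shared peaks is a smaller share of the longer list, so the percentages differ between directions.

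All of the 100 strongest peaks of each replicate were shared, and of ranks 101 to 200 the share was 99% in either list. The strongest peak without a partner ranked 194 in replicate 1 and 187 in replicate 2. For ranks 201 to 400 the share was 72% of replicate 1 peaks (interval 65.4 to 77.8) and 83% of replicate 2 peaks (77.2 to 87.6). For ranks 401 to 800 it was 33.2% of replicate 1 peaks (28.8 to 38.01) and 45.5% of replicate 2 peaks (40.7 to 50.4), and from rank 801 on it was 13.5% in replicate 1 (10.7 to 16.99). Split at the middle rank, the stronger peaks of replicate 1 were shared in 69.8% of cases and the weaker ones in 16.1% (two-sided Fisher's exact test, p = 2.03e-86). In replicate 2 the shares were 90.9% and 45.4% (Fisher's exact test, p = 1.31e-46).

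**Figure D2:**
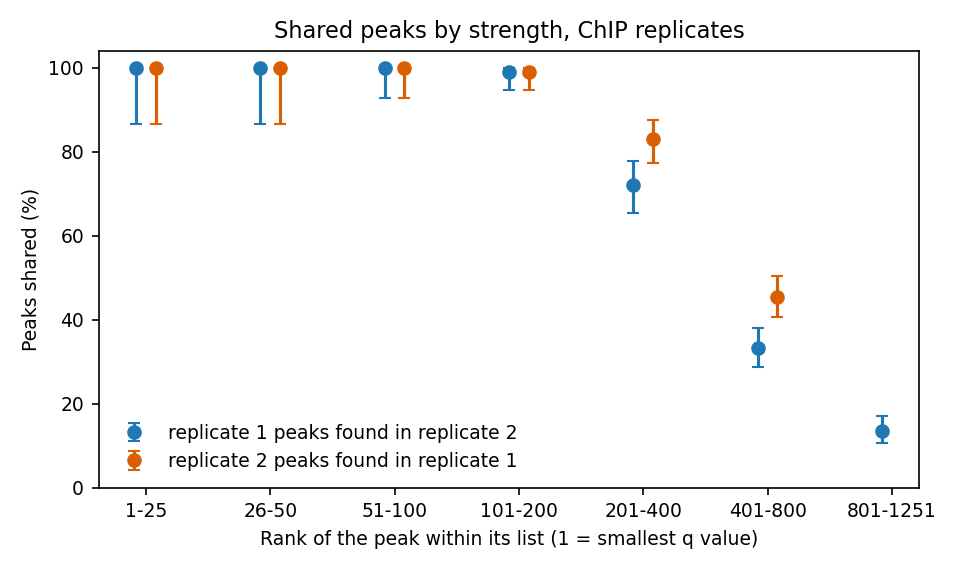
Share of peaks (%) that overlapped a peak of the other replicate by at least 1 bp, against the rank of the peak within its own list, with Wilson 95% intervals; replicate 1 peaks are blue and replicate 2 peaks orange. The share stayed at 99% or more up to rank 200 and fell to 13.5% of replicate 1 peaks beyond rank 800, and the 10 replicate 2 peaks beyond rank 800 are not drawn.

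Peak strength was ranked alike in the replicates. Over the 552 shared peaks of replicate 2 and their partners, Spearman's rho of -log10 q was 0.79 and Pearson's r was 0.90 (permutation test of pairings, p = 1e-05 for each, the smallest that 100000 permutations can give). For the 517 pairs in which each peak overlapped 1 peak of the other list, rho was 0.82 and r was 0.97. Peaks are not independent replicates, and peaks missing from either list do not enter these correlations.

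**Figure D3:**
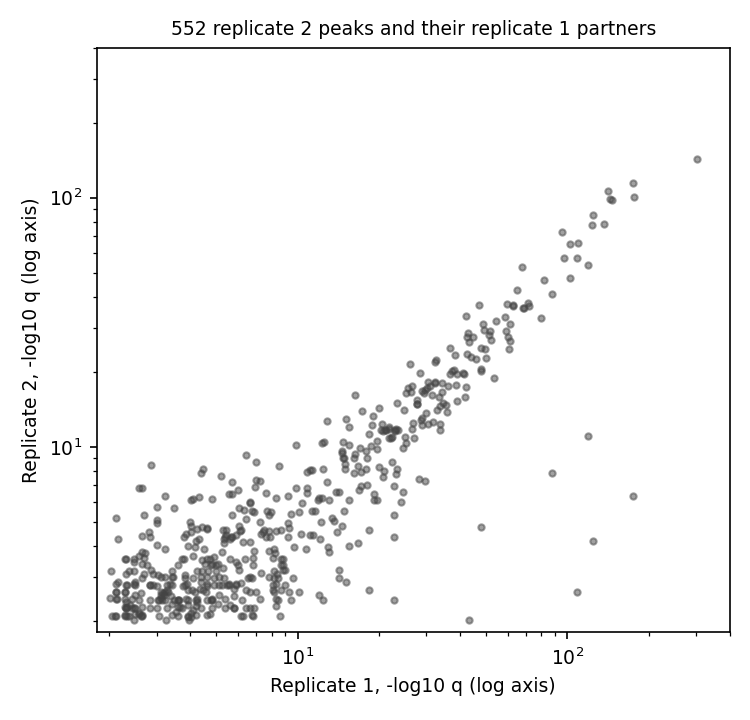
Strength (-log10 q, log axes) of 552 replicate 2 peaks against that of the replicate 1 peak each overlapped most. The points rise together with a Spearman's rho of 0.79, and the scales of the axes come from separate peak calls and cannot be compared in height.

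The combined list reached well beyond the regions found in the single libraries. Of its 2590 peaks, 549 overlapped a peak of both replicates (21.2%, Wilson 95% interval 19.7 to 22.8), 605 a peak of replicate 1 alone (23.4%) and 186 a peak of replicate 2 alone (7.18%). The remaining 1250 (48.3%, interval 46.3 to 50.2) overlapped no replicate peak. Peaks found in both replicates had a median -log10 q of 12.7. Those found in neither had a median -log10 q of 2.66 and a highest -log10 q of 9.58. By rank, 100% of the 100 strongest combined peaks and 98% of ranks 101 to 250 were found in both replicates. The share was 72.8% for ranks 251 to 500 and 21.8% for ranks 501 to 1000. From rank 1001 on it was 0.692%, and 73.9% of those peaks were found in neither replicate.

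Peaks were unevenly spread over the chromosomes relative to their spans. The expectation rests on span alone, and the cause of the unevenness was not tested. Chromosome III carried 524 combined peaks, 1.47 times the 356 expected from its span (95% interval 1.36 to 1.59; exact binomial test, adjusted p = 8.05e-19). Chromosome X carried 356 peaks, 0.776 times its expectation of 459 (0.703 to 0.855; exact binomial test, adjusted p = 1.86e-07). These correspond to 38.1 peaks per Mb on III and 20.1 per Mb on X. Both departures were present in the single libraries. Chromosome III reached 1.56 times its expectation in replicate 1 and 1.70 times in replicate 2 (exact binomial test, adjusted p = 4.64e-13 and 1.50e-12). Chromosome X was at 0.709 and 0.732 (exact binomial test, adjusted p = 2.37e-06 and 0.000817).

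The other chromosomes departed less. Chromosome I was at 1.14 times its expectation in the combined list (exact binomial test, adjusted p = 0.00536). It lay below its expectation in the single libraries, at 0.876 in replicate 1 (exact binomial test, adjusted p = 0.138) and 0.738 in replicate 2 (exact binomial test, adjusted p = 0.00276). Chromosomes IV and V were at 0.880 and 0.870 in the combined list (exact binomial test, adjusted p = 0.00573 and 0.00128). In the single libraries they ranged from 0.919 to 0.962 and did not pass the test. Chromosome II was at 1.01 (exact binomial test, adjusted p = 0.784). The ratios are shares of 1 total, so the excess on III lowers those of all other chromosomes, X among them. Leaving III out was not tried.

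**Figure D4:**
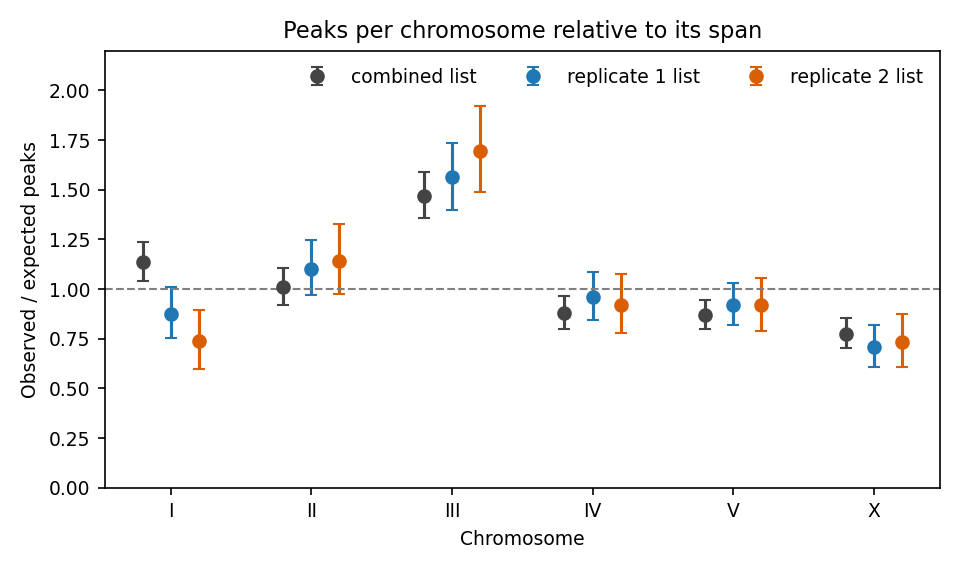
Observed number of peaks divided by the number expected from the chromosome's span, for the combined list (grey), replicate 1 (blue) and replicate 2 (orange), with exact 95% binomial intervals and a dashed line at 1. Chromosome III lies above 1 and X below 1 in all 3 lists, while I is at 1.14 in the combined list and at 0.876 and 0.738 in the replicates.

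Peaks favoured the central parts of the chromosomes. The central 50% of the spans held 1461 of the 2590 combined peaks (56.4%, exact 95% interval 54.5 to 58.3; exact binomial test, p = 7.38e-11). On chromosome V the central share was 63.1% (exact binomial test, adjusted p = 8.82e-08) and on chromosome III 59.7% (exact binomial test, adjusted p = 2.89e-05). On chromosomes I, II, IV and X it was 54.7%, 53.9%, 51.8% and 52.8%, none of which passed the test after adjustment over the 6 chromosomes. In the single libraries, III and V passed in both replicates. Chromosome I was at 55.8% in replicate 1 and 63.3% in replicate 2, and X at 47.8% and 61.0%. Both passed in replicate 2 alone (exact binomial test, adjusted p = 0.0297 for I and 0.0470 for X). Whether these shares differ between chromosomes or between replicates was not tested, nor was their cause.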

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

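The spans between the outermost combined peaks, the combined peaks with no replicate peak, the comparison without chromosome I and the removal of the strongest region or of the widest peak were alternatives chosen after the data were seen. Of 73 alternative values, 59 kept their direction and their side of the threshold, or stayed within the interval of the reported value. Replicate overlap stayed above shifted lists at 61.0% to 82.7% of replicate 2 peaks and 39.8% to 59.0% of replicate 1 peaks. Chromosome III was at 1.34 to 1.70 and X at 0.638 to 0.855, the highest value of X with nearby peaks merged. Both, and the central share at 54.4% to 61.6%, passed the test in all alternatives run. Chromosome I kept a similar ratio among the stronger 50% of combined peaks (1.13) but no longer passed the test with fewer peaks, fell below 1 among peaks found in both replicates (0.944), and was at 0.738 to 0.876 with either replicate list alone. Among combined peaks with no replicate peak, chromosome I was at 1.47 and passed the test, and chromosome II was at 0.873. Chromosome IV no longer passed the test among the stronger 50% (0.925), among peaks found in both replicates (0.981) or with either list alone (0.919 to 0.962). Chromosome V no longer passed among peaks found in both replicates (0.875) or with either list alone (0.919 to 0.922). These settings use fewer peaks, which widens the intervals, but most of these ratios also moved, and the cause was not tested. With the stronger 50% of each list, 25.097% of combined peaks were found in both replicates, and without the widest peak the combined list covered 807 kb. No paired analysis was possible because the input libraries contributed no values. The alternatives of the promoter, gene list and short sequence results were not run.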

Other observations

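All tests in this part were chosen after the data were seen. For the comparisons of replicate strength on chromosome I, the prediction was written before their values were computed. It was made for a pattern on chromosome I that had already been seen. Peaks with a q-value under 1e-10 were scarcer on chromosome X than on the autosomes. Of the 356 combined peaks on X, 8.99% passed this limit, compared with 15.2% of the 2234 autosomal peaks (two-sided Fisher's exact test, p = 0.00145). The difference was also present within replicate 1, at 7.64% on X and 18.6% on the autosomes (Fisher's exact test, p = 0.000401), and within replicate 2, at 5.71% and 19.3% (Fisher's exact test, p = 0.000286). The stronger 50% of the combined list held 181 of the 356 peaks on X, and the median -log10 q was 3.51 on X against 3.39 to 3.64 on the single autosomes.

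The strongest peak of each replicate list, near the left end of chromosome IV, had no combined counterpart, and a combined peak 2520 bp away argues against its surroundings having been left out of the combined call. Among the 20 named peaks, the combined -log10 q was at least 0.850 times the sum of the replicate values. At that ratio this region would reach 379.561, beyond the limit of 323.306 for double-precision numbers. A q-value too small to be stored may therefore have dropped the peak. The 20 peaks were picked by their combined q-values, and both replicate values of this region exceed theirs, so 379.561 is no lower bound. The ratio at the neighbouring combined peak at 261033 to 266378 was 0.205, the lowest of 549, and would predict a storable 91.4. That of the peak at 240058 to 241627 was 0.896 and would predict 399.7, beyond the limit. This ratio ranked 31 from the lowest of the 549, whose median was 1.05. It lay within the range of the 20 named peaks (0.850 to 1.16, median 0.947). Neither this limit nor a local loss of combined significance can be excluded. Whether the region holds the tagged gene or its transgene was not tested, and no biological explanation was tested.

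Combined peaks without a replicate peak were concentrated on chromosome I, with 276 of 444 (62.2%) against 974 of 2146 elsewhere (45.4%; Fisher's exact test, adjusted p = 6.96e-10 over 6 chromosomes). Larger combined q-values on I do not account for it. Within 10 strata of the combined q-value, the Mantel-Haenszel odds ratio was 4.60 (95% interval 3.23 to 6.55). The strata rest on the combined q-value, which may itself differ on I, so they cannot exclude weaker peaks there. A few clusters do not account for it either, since 14 of 15 windows of 1 Mb lay above the share elsewhere. Among combined peaks with a -log10 q of at least 10, the median log2 ratio of replicate to combined -log10 q was lower on I than elsewhere by a difference of -0.29 for replicate 1 (bootstrap 95% interval -0.35 to -0.22) and -0.43 for replicate 2 (-0.61 to -0.33), with a permutation p of 1e-05 for each, the smallest that 100000 permutations can give. The strength of replicate peaks relative to combined ones was thus lower on I in both replicates. Both ratios divide by the combined values, so the results for the replicates are not independent of each other. Whether the replicate or the combined values differ on I, and why, was not tested, and no biological explanation was tested.

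Combined peaks lay near each other, and 892 of 2590 (34.4%) had another within 2 kb. Moving every peak by up to 50 kb gave a mean of 401 and a highest count of 509 (permutation p = 1e-04, the smallest that 10000 draws can give). Peak density at the scale of these moves therefore does not account for the nearness alone. Finer variation in density is evened out by such moves and was not tested. Runs of nearby peaks that included a strong one (q-value under 1e-10) held 330 of the 892. Weak peaks flanking strong ones, by this limit, do not account for all of the clustering. Among the 2051 peaks left without these runs and other strong peaks, 562 had a neighbour. After the same moves the mean was 240 and the highest count 316 (permutation p = 1e-04, the smallest that 10000 draws can give). Peaks that flank ones just short of the limit stayed among the 562. Splitting of wider bound regions into several peaks and binding at several nearby sites may both contribute and were not told apart, and no biological explanation was tested.

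The widest combined peak spanned 117403 bp at the right end of chromosome X, from 17601432 to 17718834 (q = 8.07e-10), against 5346 bp for the next widest. Neither replicate had a peak inside it, and it made up 59.9% of the covered length on X. At the right end of chromosome I, the peak at 15063999 to 15067646 had a q-value of 8.24e-43 in the combined list, while its partners had 1.62e-06 in replicate 1 and 0.00309 in replicate 2.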
